A study of Mus musculus with 32 samples.

How the data were processed

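Liver RNA-seq of 16 mice was analysed from the deposited tables. Per the labels' protocols, flash-frozen tissue went to a service provider and libraries followed standard Illumina protocols. The aligner, counting tool, genome build and annotation are not given in the sources used here, so no coordinates are printed and strandedness is unknown. The main table holds raw counts that the authors deposited per gene symbol, 32544 rows and 32 columns, of which 0 rows lacked a name and 31962 (98.2%) matched the reference names. A second table holds scores that the authors deposited after quantile normalisation, whose scale and log base are not stated. For 1 alternative its values were averaged over R1 and R2 and multiplied by a constant, with no log taken. Because their scale is unknown, the counts of genes from this alternative are a limited check. A table of group names was not used.

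The R1 and R2 counts of an animal were summed, so a fragment is counted in both records, and the animal is the replicate. The R1 totals were 2176467 to 27851120 counts. Counts were tested with edgeR 4.0.16 (filterByExpr, TMM, robust glmQLFit and glmQLFTest), 1 mean per strain-and-sex group and all 16 animals in the fit, in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values are scaled by TMM, except for tissue lists and Gm13340. Replacing TMM by RLE moved the median log2 fold change of all genes by 0.177 for sex in NZB and 0.105 for the interaction, and by -0.0982 to 0.0553 in the other comparisons. Gene lists fixed before the data were examined were tested with camera (prior count 2, preset correlation 0.01), camera with an estimated correlation, and fry.

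Named genes followed a rule set before the data were examined: for strain comparisons the 6 highest and 6 lowest log2 fold changes, and for sex comparisons the 4 highest and 4 lowest, among genes past the threshold with a mean of at least 1 CPM and groups that did not overlap. Gm numbers, Rik clones and pseudogenes were left out, and sex chromosome genes were named apart. Ddx3y, Nnt, Fgf21, Gdf15 and the range of the mtDNA-encoded genes were always given. No gene met the rule in a strain comparison, so the member with the smallest p of some fixed lists is given there with its values, and genes named from smaller sets of libraries were chosen after their values were seen. Lists of brain and other tissue markers and the search for nuclear transcripts like mtDNA (at least 80% identity over 200 bases and 200 counts) were also written after the data were seen.

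The fit was tested on simulated counts with the real library sizes and estimated dispersions, with 50 genes changed at each fold in each comparison. The changed genes were drawn from those with a mean above 1 CPM, so recovery of weaker genes was not tested. Genes were simulated independently, without effects shared by the genes of a library. For NZB against C57 in females, 0% of genes changed 2-fold, 4% changed 4-fold, 18% changed 8-fold and 60% changed 16-fold were recovered among 16231 genes. In males the shares were 0%, 4%, 20% and 56%. Alternatives were other size factors, no filter, DESeq2, no robust step, a replicate block, only the compared groups, the quantile-normalised values, no mtDNA-encoded genes, R1 alone and each animal left out. Alternatives chosen after seeing the data left out doubted libraries or used limma sample weights.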

Results

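Liver RNA was sequenced from 16 mice aged 50 weeks, with 4 animals in each combination of strain label (BL/6C57 or BL/6NZB, below C57 and NZB) and sex. The labels spell out neither strain name further and do not state whether the strains differ in nuclear DNA, in mitochondrial DNA or in both, so strain below means the label. Each animal was listed as 2 records, R1 and R2, which the labels name like the read files of 1 library. Chi-square per degree of freedom between the R1 and R2 counts of an animal lay between 0.362 and 2.27, against at least 23.1 between any animal and its closest group mate, and the records were summed and counted as 1 sample. In 13 animals the R1 and R2 records differed by less than the sampling noise, and in NZB males 1, 2 and 3 the value was 2.27, 1.20 and 1.09. The R1 totals ranged from 2176467 counts in C57 male 4 to 27851120 in NZB female 3.

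Transcripts encoded by mitochondrial DNA (mtDNA), the subunits of the respiratory chain made inside mitochondria, took very different shares of the libraries. They made up 59.3% of counts in C57 female 4, 48.6% in NZB male 1, 45.4% in NZB male 2, 28.2% in NZB male 3 and 15.8% in C57 male 4. In the other 11 libraries the share lay between 1.08% and 6.83%. The R1 totals of these 5 libraries were between 2.18 and 10.4 M counts (M, mega), and those of the other 11 were between 20.9 and 27.85 M. Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 36.7% of counts in C57 male 4, and Grip2 took 24.1% in NZB male 1. The Wilson 95% bounds of these shares, from R1 counts and for counting error only, lay within 0.0642 percentage points of the share in R1. C57 female 1 held brain transcripts, with Mbp at 3904 CPM (counts scaled to library size), and NZB females 3 and 4 held skeletal muscle transcripts, with Acta1 at 181.7 and 89.56 CPM.

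**Figure D1:**
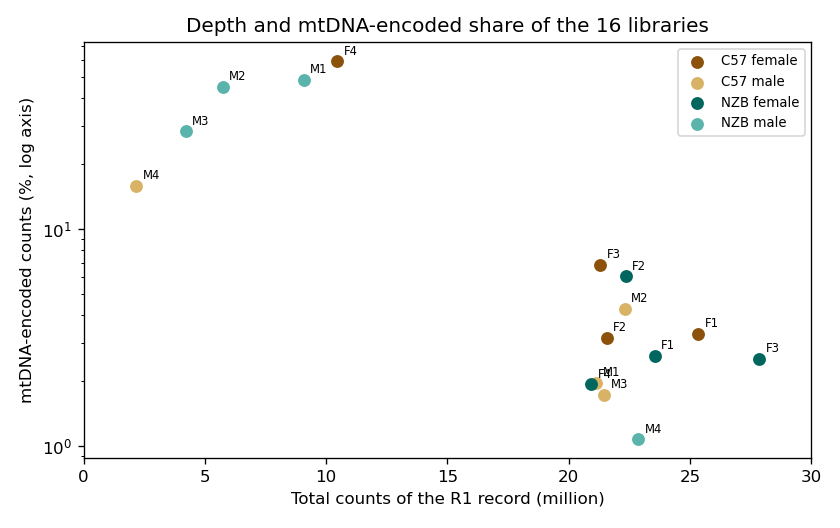
The mtDNA-encoded share of counts (percent, log axis) is plotted against the total of the R1 record (M counts) for the 16 animals, each point an animal named by sex and number and coloured by group. The 5 libraries above 10% all lie at or below 10.4 M counts.

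The sex labels were checked with Ddx3y, a gene of the Y chromosome. Its level was 59.5 ± 11.3 CPM (SD, n = 4) in C57 males and 68.4 ± 32.5 (SD, n = 4) in NZB males. In C57 females it was 0.279 ± 0.244 (SD, n = 4) and in NZB females 0.342 ± 0.351 (SD, n = 4). Nnt, a mitochondrial transhydrogenase gene, was detected in every library, at 47.3 ± 23.1 CPM in C57 females, 57.7 ± 29.2 in NZB females, 27.4 ± 15.3 in C57 males and 17.7 ± 4.49 in NZB males (SD, n = 4). Fgf21 and Gdf15, hormones of mitochondrial stress, were at 1.31 ± 1.10 and 6.41 ± 4.41 CPM in C57 females, 1.08 ± 0.576 and 5.64 ± 2.34 in NZB females, 0.707 ± 0.75 and 3.99 ± 2.72 in C57 males and 0.552 ± 0.866 and 5.09 ± 4.85 in NZB males (SD, n = 4). Xist and H2-Ea were not listed in the table.

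The nuclear gene Gm13340 has a transcript 97.6% identical to mt-Co1 over 1545 aligned bases, so reads of one can be assigned to the other. It was chosen after the values of all mtDNA-like genes had been seen. Per 10000 mtDNA-encoded counts it had 0.196 to 0.447 counts in the 4 C57 females and 28.1 to 35.2 in the 4 NZB females. Among males, the libraries labelled C57 male 1 and C57 male 3 had 30.5 and 30.9, and the library labelled NZB male 4 had 0.652. C57 males 2 and 4 had 1.45 and 0.206, and NZB males 1, 2 and 3 had 35.7, 32.6 and 30.4. Of 10 nuclear genes with such a match, 4 (Gm13340, Gm13339, Gm11410 and Gm4076) separated the females by strain label and put the same 3 male libraries nearer the other strain, and 6 did not separate the females. The groups were kept as labelled in all comparisons.

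**Figure D2:**
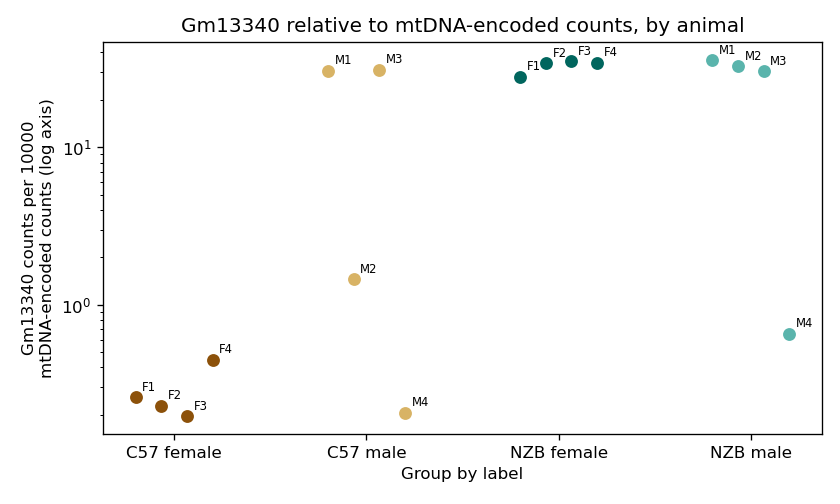
Gm13340 counts per 10000 mtDNA-encoded counts (log axis) are plotted by labelled group, each point an animal named by sex and number. The NZB females lie between 28.1 and 35.2 and the C57 females between 0.196 and 0.447, while C57 males 1 and 3 and NZB male 4 lie apart from the other males of their group.

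The first comparison asked which liver genes differed between NZB and C57 females. The mtDNA-encoded protein genes had lower values in NZB females for 13 of 13 members, with log2 fold changes from -4.09 to -2 (SE 1.11 to 1.66), and none passed the test over all genes or adjusted over the list alone. C57 female 4 stood apart in these genes, with an mtDNA-encoded share of 59.3%, against 3.16% to 6.83% in the other 3 C57 females and 1.92% to 6.05% in the NZB females. Markers of B cells and plasma cells, the antibody-producing lineage, had higher values for 15 of 18 members, among them Ighg2c, an antibody heavy chain, at 18.1 ± 19.1 CPM against 1.52 ± 0.995 (SD, n = 4). T cell and NK cell markers had higher values for 18 of 20 members, and pancreas markers for 5 of 6. Cd74, a chaperone of antigen presentation, was at 100 ± 34.2 CPM in NZB females and 39.5 ± 11.4 in C57 females (SD, n = 4). Gclc, the catalytic subunit that starts glutathione synthesis, was at 130 ± 7.06 against 54.6 ± 6.97 CPM (SD, n = 4), with an edgeR adjusted p of 0.325.

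No gene passed an adjusted p of 0.05 in females by edgeR's quasi-likelihood test over 16231 genes, with 1673 genes at an unadjusted p under 0.05. Without C57 female 1, the library with brain transcripts, 442 genes were at an unadjusted p under 0.05. Leaving out any other female in turn gave 1213 to 2142. DESeq2 was run only with all 16 animals, C57 female 1 included. DESeq2 called 468 genes, 31 higher and 437 lower in NZB, and limma on the deposited quantile-normalised values called 0. As a competitive test of gene lists, camera with a preset correlation called 18 of 35 lists, and 0 with an estimated correlation or by fry. For the B cell and plasma cell list the adjusted p was 1.23e-12 with the preset and 0.0595 with an estimated correlation, and for the mtDNA-encoded genes 0.000358 and 0.833. Without the 5 libraries of high mtDNA share and C57 female 1, a selection made after seeing the data that leaves 2 C57 females and 4 NZB females, 10 genes passed. Lifr, a cytokine receptor, was then lower by a log2 fold change of -2.92 (SE 0.278), and Mid1ip1, a regulator of fatty acid synthesis, was higher by 2.08 (SE 0.288). With all 16 animals the log2 fold change was -2.17 for Lifr (edgeR adjusted p 0.282) and 0.69 for Mid1ip1 (adjusted p 0.842). With C57 female 1 put back it was -2.37 for Lifr (adjusted p 0.118) and 0.72 for Mid1ip1 (adjusted p 0.508). Lifr stood at 1116 and 1369 CPM in the 2 C57 females retained and at 71.9 and 376 CPM in C57 females 1 and 4.

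In males, the mtDNA-encoded protein genes had higher values in NZB for 13 of 13 members, with log2 fold changes from 1.01 to 4.88 (SE 1.08 to 1.80), and 5 of them passed when adjusted over the list alone. The mtDNA-encoded share was 28.2% to 48.6% in NZB males 1 to 3, libraries of low total, and 1.08% in NZB male 4, below the 1.72% to 15.8% of the C57 males. Neutrophil markers, genes of the granules and calcium-binding proteins of that cell, had higher values for 8 of 10 members, of which 7 passed adjusted over the list alone. One of them, Mpo, the granule enzyme myeloperoxidase, was at 7.16 ± 11.7 CPM in NZB males and 0.169 ± 0.338 in C57 males (SD, n = 4), and NZB male 4 alone had 24.7 CPM. NZB male 4 also had S100a8 at 141.6 CPM, against at most 7.484 CPM in the other males. Its Gm13340 ratio of 0.652 went against its strain label. A strain difference that rests on this animal is therefore in doubt, its direction included. In limma with weights on all 16 libraries the log2 fold change was 0.86 for S100a8, 1.04 for S100a9, 0.78 for Camp and 1.49 for Elane, against 3.50, 3.38, 6.45 and 5.77 in edgeR, while for Mpo it was 7.04 against 7.81. Mpo lay between 0 and 0.677 CPM in the C57 males, so the size of its change in either fit rests on values near 0. Nuclear complex I genes had lower values in NZB males for 35 of 36 members, and B cell and plasma cell markers for 16 of 18.

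No gene passed over all genes in males by edgeR, with 695 at an unadjusted p under 0.05. DESeq2 called 23 and limma on the quantile-normalised values called 0. Camera with the preset correlation called 14 of 35 lists and 0 with an estimated correlation (adjusted p = 0.801 for the mtDNA-encoded genes). Leaving out C57 male 4 alone gave 1928 genes, 1673 of them higher in NZB. That library was the only C57 male of low total. Without it the males of low total were NZB males 1 to 3, so library total went with the strain label except in NZB male 4. Sample quality weights in limma, chosen after seeing the data, gave 9572. The weights were 0.11 for C57 male 4 and 0.0791 for NZB male 4, so that fit compared mostly NZB males 1 to 3 with C57 males 1 to 3, whose mtDNA-encoded shares were 1.72% to 4.29%. C57 males 1, 2 and 3 had weights of 4.43, 1.96 and 5.51. In both counts the C57 side thus rested mostly on C57 males 1 and 3, whose Gm13340 ratio went against the strain label. Neither count can be read as genes of strain.

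Averaged over the sexes and in the test of the strain by sex interaction, no gene passed by edgeR, with 743 and 1933 genes at an unadjusted p under 0.05. DESeq2 called 22 and 133 genes and limma on the quantile-normalised values 0 and 0. In the interaction the NZB minus C57 difference of the B cell and plasma cell markers was lower in males than in females for 16 of 18 members, with an adjusted p of 5.73e-13 with the preset, 0.0541 with an estimated correlation and 0.0106 by fry, and 12 members passed adjusted over the list alone. For the mtDNA-encoded genes it was higher in males for 13 of 13 members, with log2 values from 3.01 to 8.37 (SE 1.54 to 2.44). Averaged over the sexes their log2 fold changes lay from -0.496 to 0.85 (SE 0.756 to 1.09). Without C57 male 4, 3680 genes passed the interaction test, with NZB males 1 to 3 then the only males of low total.

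Strain effects in females and males were correlated across the 16231 genes at a Pearson r of -0.337 and a Spearman rho of -0.407. Genes are not independent replicates, so no p is given. In 99 other splits of the animals within sex the Pearson r ranged from -0.677 to 0.643, and the real value lay inside that range.

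Male and female livers of C57 differed in the genes of the classic sex-dependent liver programme. Mup20, a major urinary protein, rose from 90.8 ± 40.9 CPM in females to 14321 ± 8079 in males (SD, n = 4), a log2 fold change of 7.30 (SE 0.917, adjusted p 0.00183 by edgeR). Hsd3b5, a male-biased steroid dehydrogenase, was at 147 ± 127 against 0.32 ± 0.238 CPM, and Cyp4a12b, a male-biased fatty acid hydroxylase, at 8.07 ± 5.49 against 0.00512 ± 0.0102 (SD, n = 4). The immunoglobulin segment Igkv3-2 rose by 6.98 on the log2 scale (SE 1.21), and the 18 measured B cell and plasma cell markers were all higher in males, with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p 1.57e-14, and 0.0101 with an estimated correlation, but 0.0751 by fry). T cell and NK cell markers were higher in males for 16 of 20 members, fat tissue markers for 6 of 7 and red blood cell markers for 6 of 8. In NZB, Igkv3-2 went the other way, at 12.1 ± 8.96 CPM in females and 0.788 ± 0.795 in males (SD, n = 4). Of the 4 C57 females, 1 had any Cyp4a12b count. The sulfotransferases Sult2a3 and Sult2a5 fell in males, from 76.1 ± 40.2 and 68.3 ± 35.6 CPM to 0.124 ± 0.148 and 0.215 ± 0.308 (SD, n = 4). Sult2a6 was at 24.9 ± 12.5 CPM in females and 0.0846 ± 0.169 in males (SD, n = 4), with any count in 1 of 4 males. The cytochrome P450 Cyp3a44 fell from 1330 ± 1256 to 2.53 ± 2.60 CPM (SD, n = 4). Members of these gene families resemble each other, so counts can be shared between them.

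In C57, 37 genes passed over all genes, 16 higher and 21 lower in males. The mtDNA-encoded protein genes were not among them, with log2 fold changes from -3.66 to 0.573 (SE 1.07 to 1.70). Of the female-biased liver genes fixed beforehand, 12 of 30 fell over all genes and 21 fell adjusted over the list alone (camera adjusted p 1.15e-71, and 5.27e-06 with an estimated correlation). Of the male-biased genes, 7 of 36 rose over all genes, and adjusted over the list alone 27 rose and 1 fell (adjusted p 1.04e-47, and 0.00198 with an estimated correlation). The count depended on single libraries: it was 12 without C57 male 1 and 13 without C57 male 3, the libraries whose Gm13340 share went against the label, and 22 without C57 female 2 or C57 female 3. It was 10 without C57 male 1, C57 male 3 and NZB male 4.

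**Figure D3:**
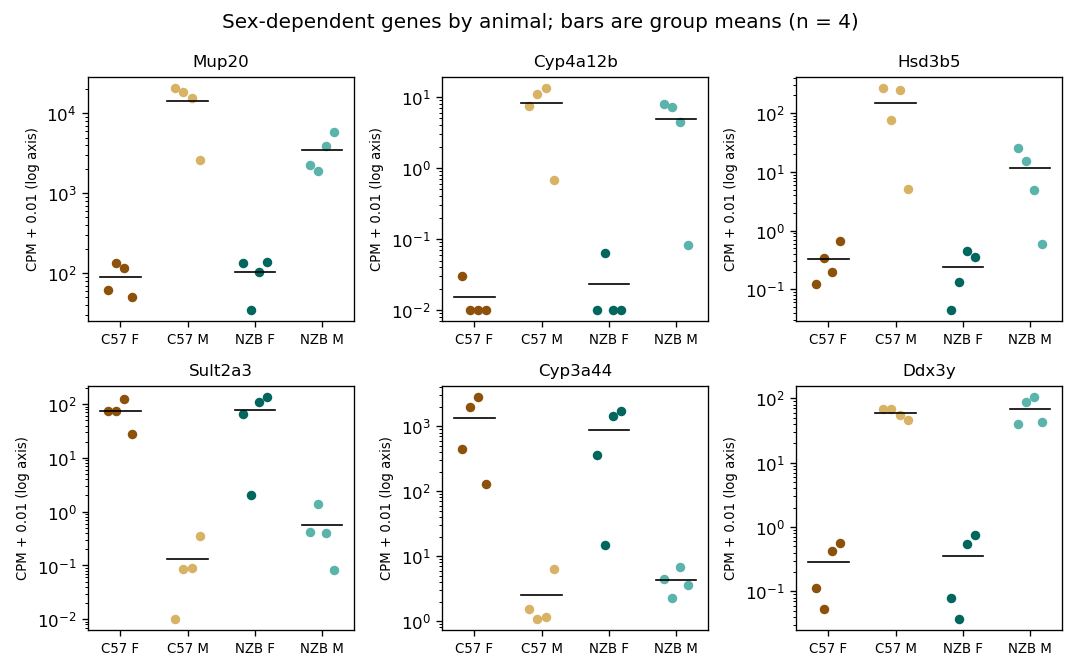
Levels of 6 genes (CPM + 0.01, log axis) are plotted by group, each point an animal and each bar the group mean (n = 4). Mup20, Cyp4a12b, Hsd3b5 and Ddx3y are higher in males and Sult2a3 and Cyp3a44 are higher in females of both strains.

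In NZB, Mup20 rose from 103 ± 48.0 CPM in females to 3493 ± 1833 in males (SD, n = 4), a log2 fold change of 5.09 (SE 0.828, adjusted p 0.0222 by edgeR). Slco1a1, an organic anion transporter, rose from 2.97 ± 1.23 to 71.6 ± 56.5 CPM, and Nat8f5 from 0.0687 ± 0.0582 to 7.80 ± 5.14 (SD, n = 4). Cyp4a12b was at 4.92 ± 3.56 CPM in males and 0.0135 ± 0.027 in females (SD, n = 4), with any count in 1 of 4 females. Cyp3a16, Cyp3a44, Sult2a2 and Sult2a3 fell in males, Sult2a2 from 343 ± 168 to 1.73 ± 0.825 CPM (SD, n = 4). The Y-linked genes Ddx3y, Eif2s3y and Uty rose by 7.64, 7.21 and 7.42 on the log2 scale.

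In NZB, 23 genes passed over all genes, 12 higher and 11 lower in males. Of the female-biased genes, 8 of 30 fell over all genes, and adjusted over the list alone 21 fell and 1 rose (camera adjusted p 1.97e-21, and 0.0026 with an estimated correlation). Of the male-biased genes, 3 of 36 rose over all genes, and adjusted over the list alone 13 rose and 1 fell (adjusted p 6.14e-07, 0.455 with an estimated correlation, and 0.0466 by fry, which tests the list on its own). B cell and plasma cell markers, all higher in C57 males, were lower in NZB males for 15 of 18 members. Their camera adjusted p was 0.000447, and 0.455 with an estimated correlation, and by fry it was 0.0328. The mtDNA-encoded genes were higher in males for 13 of 13 members, with log2 fold changes from 3.58 to 5.11 (SE 1.18 to 1.76). All passed adjusted over the list alone and none over all genes, and NZB males 1, 2 and 3 had the high mtDNA-encoded shares given above. The count was 2487 without NZB male 4, and DESeq2 called 2807 with all animals. Without NZB male 4 the NZB males had R1 totals of 4.208 to 9.068 M counts, against 20.93 to 27.85 M in the NZB females. Sex and library total cannot be told apart in that count. Without NZB females 1, 2, 3 and 4 in turn the count was 8, 14, 4 and 5, and without NZB males 1, 2 and 3 in turn it was 7, 4 and 8.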

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

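All tests of explanations below were chosen after the results were seen, and so were the brain and muscle lists and Gm13340. The strain by sex test of the gene lists and the outlier test were planned. Dixon's test at 95% marked an outlier in 30 of 104 groups of 4 animals. Chance flags about 1 in 20 groups where values are normally spread, which CPM of genes near 0 are not. Where the other animals of a group had 0, any count was marked, as for Cyp4a12b and Sult2a6. The 30 can therefore not be set against that rate.

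C57 male 4 lay far from its group in many measures. It had 2.18 M (mega) R1 counts (others 21.1 to 22.3), 6487 genes with at least 10 counts (others from 12719), 36.7% Lars2 and 9.89% Grip2. Its brain list summed to 389 CPM and its muscle list to 14.8 CPM. NZB males 3, 2 and 1 and C57 female 4, also of low total, had brain sums of 313.3, 179.2, 96.61 and 98.51 CPM. Libraries of higher total, C57 female 1 apart, had 29.2 to 56.17 CPM. C57 male 4 was also highest of its group for Sult2a6 (0.338 CPM), Sult2a5 (0.677), Cyp3a44 (6.43), Sult2a2 (2.71) and Uty (57.2). C57 female 4 stood apart in its mtDNA-encoded share (59.3%), Lars2 (2.41%), Grip2 (0.56%), Eif2s3y (0.7 CPM) and Uty (7.6 CPM).

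C57 female 1 had 15944 genes with at least 10 counts, a brain sum of 9408 CPM, a muscle sum of 24.6 CPM and Cyp4a12b at 0.0205 CPM. NZB female 2 stood apart in the mtDNA-encoded share (6.05%), Lars2 (0.114%), Cyp4a12b (0.054 CPM), Sult2a2 (93.3 CPM) and Gdf15 (9.12 CPM). NZB female 1 had a Gm13340 ratio of 28.1, below the 34.1 to 35.2 of the other 3. NZB male 4 stood apart in Gm13340 (0.652), Slco1a1 (156 CPM) and Sult2a2 (0.492 CPM), and NZB male 3 had Sult2a6 at 1.74 CPM where the other 3 had 0.

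The strain effect differed between the sexes for 14 lists by camera with the preset correlation, for 0 with an estimated correlation, and by fry, which tests each list on its own, for the B cell and plasma cell markers (0.0106). NZB males 1 to 3, of low total, stand on one side of this contrast. Without the 5 libraries of high mtDNA share and C57 female 1, a choice made after seeing the data, NZB male 4 was the only NZB male. With the preset correlation lists then lay in both directions, and the NZB side in males rested on that animal. With all 16 animals, the mtDNA-encoded genes were relatively higher in NZB males (adjusted p 1.15e-06). The other 13 lists were relatively lower: B cell and plasma cell markers (5.73e-13), T cell and NK cell markers (1.42e-08), mitochondrial ribosome (1.22e-06), nuclear complexes II to V (5.89e-06) and nuclear complex I (0.000115). Antioxidant and NRF2 genes, antigen presentation and the cytosolic ribosome had 0.00025 each, and fatty acid oxidation and periportal hepatocyte genes 0.000459 each. Bile acid synthesis and transport had 0.000637, male-biased liver genes 0.00089 and cholesterol synthesis 0.00188.

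The high mtDNA-encoded share of 5 libraries was weighed first. A strain or sex difference as the whole cause is argued against by 59.31% in a C57 female. NZB male 4 had 1.076%, but its strain label is in doubt. A low library yield may account for it, since the highest R1 total of the 5 was 10.44 M counts and the lowest of the others was 20.93 M. Because 3 of the 5 are NZB males, a part due to strain in males stays open.

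The brain transcripts in C57 female 1 were weighed next. Mbp was at 3904 CPM, Snap25 at 808.9 and Gfap at 801.5. Greater depth is argued against, since the deepest library, NZB female 3, had a brain sum of 30.74 CPM. All 10 brain genes exceeded 10 times the median of the other 15 animals, but the list was written after brain transcripts had been seen in this library, so this restates the pattern. Brain RNA in the library was therefore left open, and no biological explanation was tested.

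The Gm13340 ratio against the strain label in C57 males 1 and 3 and NZB male 4 was weighed last. Transcription of the nuclear copy is argued against for Gm13340: its CPM varied 32.6-fold over the libraries with a high ratio, while the ratio varied 1.27-fold. Over the same libraries the ratios of the other genes that separated the females varied more. They ran from 2.65 to 17.3 for Gm11410, 3.93 to 16.9 for Gm13339 and 0.114 to 1.16 for Gm4076, so the argument covers Gm13340 alone. Mixing of a large share of another library is argued against by 30.5, inside the NZB female range, for C57 males 1 and 3. For NZB male 4 it is argued against by 0.652 against at least 28.1. Mixing of a small share stays open. NZB male 4 lay above the 0.447 reached in C57 females, and so did C57 male 2 at 1.45. Mislabelled libraries may account for the ratios against the label. This cannot be told from a mtDNA variant carried by these animals, since 0 of 3 nuclear strain markers with any count separated the females. If BL/6NZB stands for NZB mtDNA on a BL/6 nuclear background, which the labels do not state, no nuclear marker could separate the labels, and the strain comparisons would compare mtDNA.

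Other splits of the animals say nothing about chance for the counts of genes by strain, since the real counts were 0 and no split can give fewer. So 35 of 35 splits reached the real count in females and 35 of 35 in males, and 100 of 100 averaged over sexes and for the interaction. The highest other counts were 61, 8726, 8375 and 7944, and the last 3 point to a structure of the samples other than the labels. For sex in C57, 6 of 35 splits gave at least the real 37 genes, with up to 3158, so chance is not excluded for that count. For sex in NZB, 1 of 35 splits, the real one, gave 23, and the highest other gave 0. This argues against chance but cannot exclude it, since 35 splits allow no share below 1 of 35.

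For the sex-biased liver lists in both strains, 1 of 35 splits, the real one, gave a list mean as large for each. This argues against chance but cannot exclude it, since 35 splits allow no share below 1 of 35. The measure was the mean log2 difference of male minus female over a list, less that over all genes. In C57 it was -4.77 for the female-biased list, against at most 3.28 in size in another split, and 3.07 for the male-biased list, against at most 2.79. In NZB it was -4.38, against at most 2.89, and 1.82, against at most 1.25.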

How the results depend on the processing

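The sample weights and the 3 sets of libraries left out were chosen after seeing the data; the other alternatives were planned. None of the genes named as past the threshold for sex in C57 or NZB reversed its direction under RLE, no filter, DESeq2, the replicate block, sample weights or with libraries left out, and the other alternatives were run for the counts of genes only. Of the alternative values of these genes 221 stayed past the threshold and 115 did not. For strain in males Saa1 did reverse, from a log2 fold change of 3.86 to -1.26 with sample weights, and it was not alone. Fgl1 went from 2.04 to -1.77 and Apcs from 1.97 to -1.59, while Lcn2 (5.64 and 0.435) and Orm2 (4.94 and 0.133) kept their sign. The cause of the differences below was not tested, except that fewer samples were fitted where libraries were left out.

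DESeq2 called 468 genes for strain in females, 23 in males, 22 averaged over sexes, 133 for the interaction, 199 for sex in C57 and 2807 for sex in NZB. Sample weights gave 24, 9572, 5993, 8042, 470 and 9135 in that order. Without the 5 libraries of high mtDNA share and C57 female 1 the counts were 10, 94, 28, 64, 176 and 125. Without the 5 libraries alone they were 5 in males, 3 for the interaction and 76 for sex in C57. These sets leave NZB male 4 as the only NZB male, assumed to vary like the other groups. Without the 3 males whose Gm13340 ratio went against the label, 2 genes were called averaged over sexes, 10 for sex in C57 and 3005 for sex in NZB. That set leaves NZB males 1 to 3, all of low total, so sex in NZB went with library total there. R1 alone gave 1 gene for the interaction, and RLE gave 13 for sex in NZB. The compared groups alone gave 12 for sex in C57 and 2106 for sex in NZB. A replicate block gave 22 and 11, though the labels do not state that the replicate numbers pair the animals. Deviations from the group mean correlated at r of -0.803 to 0.498 over 24 pairs of animals of the same number, above 0.1 in 8.

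Leaving out each animal in turn gave 0 to 1928 genes for strain in males, 0 to 3 averaged over sexes, 0 to 3680 for the interaction, 12 to 50 for sex in C57 and 4 to 2487 for sex in NZB. The highest counts came without C57 male 4 (1928, 3680 and 50) and without NZB male 4 (3 and 2487).

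Lists called fell with an estimated correlation from 18, 14, 2 and 14 to 0 for strain in females, males, the average and the interaction, from 12 to 4 for sex in C57 and from 19 to 1 for sex in NZB. Fry called 0, 0, 0, 1, 3 and 5 in that order. Without the 5 libraries and C57 female 1 camera with the preset correlation called 6 in females, and 0 were called with an estimated correlation or by fry. For males, the average and the interaction, the lists in this set rested on NZB male 4 as the only NZB male. The direction in females turned from 17 higher and 1 lower to 1 higher and 5 lower. In females the nuclear complex I, nuclear complexes II to V and both ribosome lists turned from higher to lower, and a replicate block gave 4 for the average.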

Other observations

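The genes below were chosen after seeing the values, and so were the tissue lists. NZB male 4 had the acute phase proteins Saa1 at 3966 CPM, Orm2 at 1350 and Hp at 12810, and the iron-binding protein Lcn2 at 482.8. In the other 15 animals Saa1 reached 189 CPM, Orm2 112, Hp 3058 and Lcn2 27.35. Hamp, the iron hormone hepcidin, was at 1.258 CPM in NZB male 4 and at 15.66 or above in the others. These genes were picked for this animal, whose strain label is in doubt, so their values say nothing about strain. NZB female 2 had the clock gene Arntl at 13.45 CPM, against up to 7.429 in the others, and Pck1, an enzyme of glucose synthesis, at 1958 CPM, against up to 1528.

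Skeletal muscle transcripts summed to 947.5 CPM in NZB female 3 and 640 CPM in NZB female 4, with Acta1 at 181.7 and 89.56 CPM. The kidney list summed to at most 0.5278 CPM in any library, lung to 1.296, testis to 0.2575 and heart to 7.286.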
